A study of Homo sapiens with 11 samples.

How the data were processed

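The series measured RNA bound by the methyltransferase proteins METTL3, METTL14 and METTL16 by RNA immunoprecipitation and sequencing (RIP-seq). HEK293T, a line derived from human embryonic kidney, was made to overexpress 1 FLAG-tagged protein at a time. Per the labels' protocols, cells were cross-linked with 0.75% formaldehyde for 10 min, lysed, sonicated and precipitated with an antibody against FLAG. RNA from the precipitate (RIP) and from lysate taken without antibody (input) was sequenced. The labels speak of ribosomal RNA removal in 1 place and of a stranded mRNA library kit in another. Which of these set the RNA makeup of the libraries was not settled here. There were 11 libraries in 6 groups: 2 inputs and 2 RIPs for METTL3, 2 inputs and 2 RIPs for METTL14, and 1 input and 2 RIPs for METTL16. The series' design text calls the replicates biological. No precipitation with a control antibody, or from cells without a FLAG-tagged protein, was used here, so a difference between RIP and input holds everything that the precipitation enriches.

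The authors deposited 3 tables of TPM, a transcript's share of its library, 1 table per protein. Per the submitters' processing notes, STAR (version not given in the sources used here) and RSEM 1.2.31 were used with the genome build GRCh38. The gene annotation is not given in the sources used here. Each table held 26922 rows, of which 92 were ERCC spike-ins, the synthetic RNAs added as a reference, and 26830 were genes. No column was left unmapped to a sample. Columns summed to 1000000 including the spike-ins, so TPM is a share of the library: where 1 RNA takes more of it, every other RNA falls. TPM also divides by length, so short RNAs take a larger share than their number of reads would give. The tables keep no read depth. Depth and counting error are therefore unknown, and precision rests on the spread between libraries alone. Of the gene rows, 3256 were at 0 in all 11 libraries.

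Gene names were those of the tables. Against RefSeq's gene table of GRCh38.p14, 23987 gene rows matched by symbol, 1395 by synonym and 1448 did not match. Coordinates are from that table, 1-based. Rows of multicopy genes that held identical values are named as such, since reads of such copies cannot be told apart.

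The test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with an intensity trend) on log2(TPM + 1), without spike-in rows. Genes entered at 1 TPM or more in at least 2 of the 11 libraries, which left 13486 genes, 11639 of them protein-coding. A gene could pass through RIP libraries alone, and such a gene can hardly be called lower in RIP. One fit with 6 groups shared the estimate of the spread (5 residual degrees of freedom, median prior degrees of freedom 6.89), which the METTL16 comparison needs because its input is 1 library. That library is assumed to vary as the other groups do. Each RIP was compared with its input, and the RIP minus input differences were then compared between proteins. Genes were called at a two-sided Benjamini-Hochberg adjusted p under 0.05. Differences are on the log2(TPM + 1) scale, which understates changes of low genes. A relative log2 difference is a gene's or list's value minus the median of all genes tested. Overlaps of calls were tested with Fisher's exact test (two-sided). In the comparison of alternatives an infinite odds ratio was replaced by that with 0.5 added to each cell, while the overlap tables keep it as infinite.

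The 24 gene lists were m6A writer complex, m6A readers and erasers, SAM and methionine cycle, nuclear long noncoding RNAs, abundant Pol III and RNP RNAs, spliceosomal snRNAs, small nucleolar and Cajal body RNAs, snoRNA host genes, replication-dependent histones, cytosolic ribosomal proteins, translation initiation factors, mitochondrially encoded mRNAs, mitochondrially encoded rRNAs and tRNAs, mitochondrial ribosomal proteins, nuclear-encoded oxidative phosphorylation, ER chaperones and folding enzymes, cholesterol biosynthesis, zinc finger genes, solute carriers, reported m6A-bearing mRNAs, immediate early and stress genes, proliferation genes, spliceosome protein genes, and contaminating cell markers. TERC belongs to both the nuclear long noncoding RNA and the Pol III and RNP lists. Lists with at least 3 members tested were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the lists of a comparison. camera compares a list with all other genes, while fry tests a list against 0.

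Named genes followed a rule. Per RIP comparison it took the 12 largest rises and 10 largest falls among called genes with a mean of at least 5 TPM in the higher group and the same direction in every pair of RIP and input library, without METTL3, METTL14 and METTL16. Per difference between proteins it took the 6 highest and 6 lowest. It added up to 4 called members per list, those with the largest absolute difference, and always METTL3, METTL14, METTL16, WTAP, MAT2A, MALAT1, MYC and RN7SK. Groups, tests, lists, this rule and most alternatives were fixed before the data were examined. Alternatives tried were other pseudocounts (0.1 and 5), other filters, median-of-ratios and quantile scaling, rescaling without small RNAs and the overexpressed genes, fits of each table alone, no variance trend, a replicate block, leaving out each library except the only METTL16 input, and other thresholds. Chosen after seeing the data were rescaling without spike-ins, the same also without small RNAs and overexpressed genes, METTL16 RIP against the 4 METTL3 and METTL14 inputs, and the writer list without METTL3 and METTL14.

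The fit was tested on simulated data with 13486 genes. Of genes changed by 1 log2 unit it recovered 93% for METTL3, 92% for METTL14 and 90% for METTL16. Of genes changed by 0.5 it recovered 54%, 38% and 29%, and it made 5, 1 and 3 false calls in these comparisons. Each size was given to 100 genes. All other values were drawn around the same mean in every group with independent normal noise, and the METTL16 input was given the spread of the other groups. A shift of most genes, correlated genes and the spike-in share of the METTL16 input were not simulated. Recovery and false calls under these are unknown. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.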

Results

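The data were 11 TPM profiles of HEK293T cells overexpressing FLAG-tagged METTL3, METTL14 or METTL16. METTL3 and METTL14 are the core of the complex that writes N6-methyladenosine (m6A) on mRNA, and METTL16 is a separate m6A methyltransferase known to act on U6 snRNA and on the MAT2A transcript. The series' title states the aim of finding the transcripts each protein binds. Values are means ± SD over 2 libraries (n = 2), except for METTL16 input, which is 1 library. TPM carries no read depth, so the depth behind each value is unknown. Between 8476 and 13695 genes reached 1 TPM in 10 libraries, and 4563 in the METTL16 input. Replicate libraries correlated at 0.988 to 0.996 across tested genes on the log2 scale, and the SD of their gene-wise differences was 0.13 to 0.22.

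A few small structured RNAs took most of every library except the METTL16 input, where spike-ins did. 7SL RNA, the RNA of the signal recognition particle, held 75.9% ± 1.84 of TPM in METTL3 input and 31.3% ± 0.359 in METTL3 RIP, and 78.2% ± 1.00 and 28.9% ± 0.683 for METTL14. For METTL16 it held 35.1% in the input and 41.4% ± 2.88 in RIP. Spike-ins diluted that input: of TPM without spike-ins, 7SL held 79.5% there and 41.8% ± 2.87 in METTL16 RIP, against 78.5% ± 1.41 and 80.3% ± 1.19 in the METTL3 and METTL14 inputs. 7SK RNA, which holds the elongation factor P-TEFb in an inactive complex, went from 0.0243% ± 0.00262 to 11.2% ± 1.18 (METTL3), from 0.0483% ± 0.00761 to 11.6% ± 0.470 (METTL14) and from 0.0271% to 23.5% ± 0.0413 (METTL16). RMRP and RPPH1, the RNAs of RNase MRP and RNase P, together held 0.0811% ± 0.00931 of METTL3 input and 18.4% ± 1.42 of its RIP, 0.0577% ± 0.0122 and 14.6% ± 0.625 for METTL14, and 0.188% and 9.63% ± 1.07 for METTL16. Small nucleolar and Cajal body RNAs held 1.15% ± 0.178 and 11.97% ± 1.89, 0.851% ± 0.0911 and 10.3% ± 1.90, and 1.09% and 7.56% ± 1.25. Y and vault RNAs moved the other way, from 6.74% ± 0.462 to 1.32% ± 0.138, from 6.80% ± 0.378 to 1.14% ± 0.0119, and from 2.64% to 1.13% ± 0.0255. Spike-ins held 55.9% of the METTL16 input and 1.00% to 3.79% of the other 10 libraries. Of TPM without spike-ins, the METTL16 input held 0.0615% 7SK, 0.426% RMRP and RPPH1, 2.47% small nucleolar and Cajal body RNAs and 5.98% Y and vault RNAs. All other genes together held 3.13% of the METTL16 input (7.09% without spike-ins, against 9.12% ± 0.488 and 8.37% ± 0.378 for METTL3 and METTL14 inputs), 8.82% ± 0.416 and 8.15% ± 0.384 of the METTL3 and METTL14 inputs, and 12.04% ± 0.685, 22.2% ± 1.06 and 9.06% ± 1.07 of the METTL3, METTL14 and METTL16 RIPs.

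**Figure D1:**
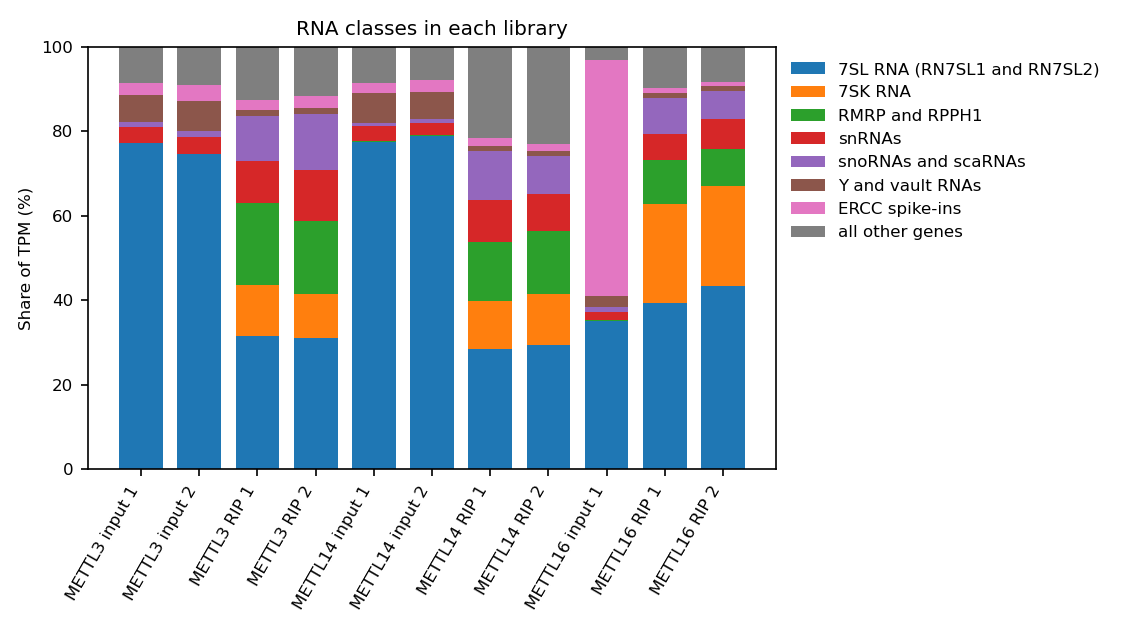
Share of TPM (%) held by each RNA class in each of the 11 libraries, as stacked bars. 7SL RNA held 75.9% and 78.2% of the METTL3 and METTL14 inputs on average, and spike-ins held 55.9% of the METTL16 input.

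These shares set the scale of every comparison. The median gene tested was higher in RIP than in input by 0.68 on the log2 scale for METTL3, 1.38 for METTL14 and 0.87 for METTL16, so changes are given below relative to that median as well. With libraries scaled by median ratios, these medians were -0.04, -0.03 and -0.01. A value relative to the median still holds part of the scale, because the pseudocount holds back low genes more than abundant ones. For METTL16 that scaling moved cytosolic ribosomal proteins from 0.93 to -0.13 relative to the median gene, and replication-dependent histones from 0.94 to 0.11.

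The overexpressed transcripts were examined first, since they check the labels. METTL3 mRNA (chromosome 14, 21498138 to 21511340) stood at 308 ± 12.5 TPM in METTL3 inputs, 79.5 times the highest other input library. METTL14 mRNA (chromosome 4, 118685392 to 118715430) stood at 16.6 ± 1.03 TPM in METTL14 inputs, 40.6 times the highest other input. METTL16 mRNA (chromosome 17, 2415715 to 2511888) stood at 9.51 TPM in the METTL16 input, 2.02 times the highest other input and 4.47 times without spike-ins. Each was far higher in its own RIP, at 3667 ± 226 TPM (METTL3), 4426 ± 51.1 TPM (METTL14) and 405 ± 75.5 TPM (METTL16). The log2 differences from input were 3.57 ± 0.11 (SE, adjusted p = 1.3e-10), 7.97 ± 0.10 (2.3e-13) and 5.26 ± 0.15 (3.9e-10) in the limma fit. Relative to the median gene they were 2.89, 6.59 and 4.39. In the other proteins' RIPs METTL3 mRNA stood 1.11 (METTL14) and 0.93 (METTL16) above the median gene, METTL14 mRNA 1.19 (METTL3) and 0.05 (METTL16), and METTL16 mRNA at -0.51 (METTL3) and -0.48 (METTL14).

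**Figure D2:**
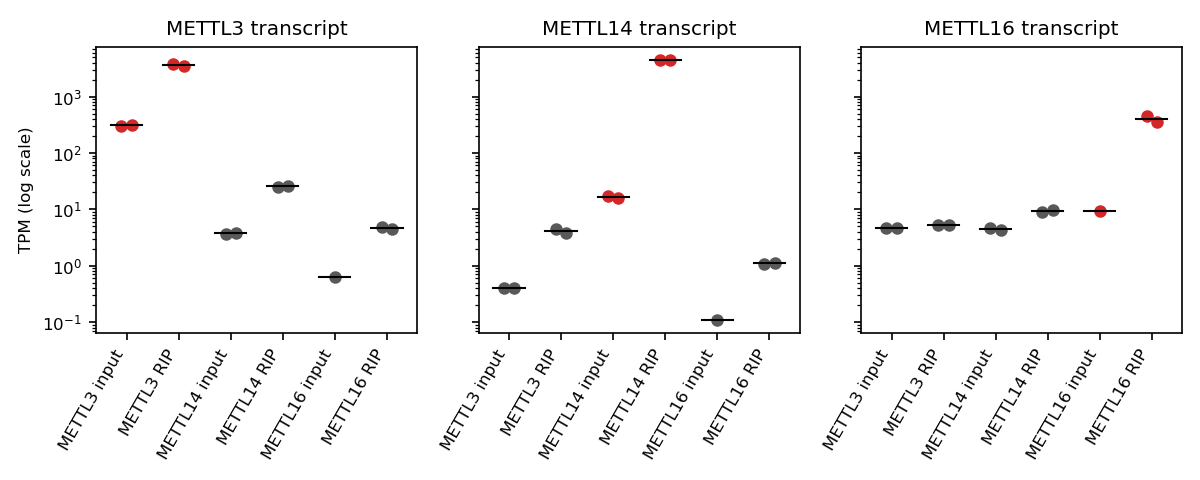
TPM (log axis) of the METTL3, METTL14 and METTL16 transcripts in the 6 groups; points are libraries, lines are group means, and red marks the groups overexpressing that gene. Each transcript was highest in the RIP of its own protein, at 3667, 4426 and 405 TPM.

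The METTL3 comparison asked which RNAs were enriched with METTL3 over input. Noncoding RNAs led the rises. 7SK (RN7SK, chromosome 6, 52995620 to 52995951) rose from 243 ± 26.2 to 111615 ± 11821 TPM, RMRP (chromosome 9, 35657750 to 35658019) from 397 ± 44.2 to 97685 ± 8051 TPM, and RPPH1 (chromosome 14, 20343071 to 20343411) from 415 ± 48.8 to 86032 ± 6163 TPM, with log2 differences of 8.84, 7.94 and 7.70. The Cajal body RNAs SCARNA7, SCARNA12, SCARNA10 and SCARNA5, which guide modification of spliceosomal snRNAs, rose by 7.67, 7.23, 7.19 and 7.05. SNAR-B1 and SNAR-B2, whose rows were identical, rose by 7.11. The microRNA genes MIR3687-1 and MIR3687-2 (identical rows) and MIR6516 were listed at 0 in both inputs and at 670 ± 183 and 97.6 ± 20.6 TPM in RIP, and the difference of MIR3687-1 (9.36) was the largest of all. Adjusted p was 4.4e-10 or lower for all of these. The names MIR3687-1 and MIR3687-2 did not match the RefSeq table. For microRNA genes here and below, the values do not show whether reads came from a precursor or from a longer RNA over the same place. The largest falls included ribosomal, Y and vault RNAs: RNA28S5 (28S rRNA, 469 ± 34.3 to 11.1 ± 0.742 TPM), RNA5S9 (5S rRNA, 30.2 ± 15.9 to 0.995 ± 0.177), RNY4, RNY1 and RNY3, and VTRNA1-3, with log2 differences of -5.28, -3.87, -2.97, -2.52, -2.25 and -2.37. MIR621 fell by 3.04 and the Mediator subunit gene MED18 by 2.10. SNORA100 (11.7 ± 0.721 TPM in input) and MIR612 (5.37 ± 0.658) were listed at 0 in both RIPs. Adjusted p was 0.0041 or lower for these falls.

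Among longer RNAs in METTL3 RIP, all 11 nuclear long noncoding RNAs tested rose. TERC, the telomerase RNA, rose by 5.75, MALAT1 (chromosome 11, 65497738 to 65506516) from 4.62 ± 0.0283 to 147 ± 10.2 TPM, NEAT1, the scaffold of paraspeckles, by 4.37 and FTX by 1.93. The list stood 1.00 above the median gene (camera adjusted p = 0.023). Small nucleolar and Cajal body RNAs (268 of 295 rose, 6 fell) stood 1.79 above it (3.5e-05), and the snoRNA host genes (20 of 22 rose, led by TAF1D, SNHG25, SNHG3 and SNHG6) 1.03 above it (0.023). Of the immediate early and stress genes, 15 of 15 rose, with EGR1, GADD45B, FOSB and JUN up by 2.71, 2.30, 2.20 and 2.02, and the list stood at 0.72 (0.023). Replication-dependent histones (52 of 56 rose) stood at 0.38 (0.046), with HIST1H4K, HIST1H2AD, HIST2H2AC and HIST1H1D highest. Zinc finger genes (332 of 392 rose, 16 fell, ZNF121, ZNF721, ZNF354B and ZNF767P highest) stood at 0.09 (0.042). On the low side, cytosolic ribosomal protein mRNAs (40 of 79 rose, 22 fell) stood at -0.35 (1.0e-05). RPLP0 went from 1155 to 273 ± 3.93 TPM and RPS2 from 3481 to 844 ± 21.3 TPM, while RPL23 and RPL35 rose by 1.99 and 1.81. Solute carriers (118 of 204 rose, 33 fell) stood at -0.36 (3.1e-04), with SLC25A27, SLC25A36, SLC25A16 and SLC25A35 highest. The abundant Pol III and RNP RNAs (5 of 13 rose, 8 fell) stood at -1.89 (2.6e-04) as a mix of risen 7SK, RMRP, RPPH1, TERC and RNY5 (4.34) with fallen 7SL, vault and other Y RNAs, and at 0.01 with quantile normalization. With an estimated correlation every one of these camera calls was lost (adjusted p = 0.591 for the Pol III list and 0.915 for the others). Median-of-ratios scaling ended those of histones (0.19, 0.354) and Pol III and RNP RNAs (-2.21, 0.898). Under it 14 of 79 cytosolic ribosomal proteins rose and 56 fell, and 38 of 180 solute carriers rose and 122 fell.

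Lists that camera did not call for METTL3 are given by value. Median differences relative to all genes were 1.12 for the m6A writer complex (7 of 8 rose, 1 fell, with METTL3 itself a member), 0.51 for m6A readers and erasers (12 of 16 rose), 0.78 for spliceosomal snRNAs (11 of 15 rose), 0.48 for spliceosome protein genes (30 of 37 rose), 0.36 for oxidative phosphorylation (61 of 76 rose), 0.25 for mitochondrial ribosomal proteins (66 of 77 rose), 0.24 for proliferation genes (21 of 25 rose), 0.11 for ER chaperones (15 of 20 rose), -0.17 for translation initiation factors (24 of 40 rose), -0.17 for cholesterol biosynthesis (14 of 22 rose), -0.17 for reported m6A-bearing mRNAs (22 of 27 rose) and -0.23 for the SAM and methionine cycle (10 of 17 rose, 5 fell). Their camera adjusted p ranged from 0.056 to 0.912. With median-of-ratios scaling camera called the writer complex (1.04, adjusted p = 0.029) and cholesterol biosynthesis (-0.30, 0.026), and the median of ER chaperones turned to -0.03. RBM15 and ZC3H13 of the writer complex rose by 2.52 and 1.80, WTAP from 2.94 ± 0.0354 to 12.7 ± 0.905 TPM, HNRNPA2B1 and YTHDF2 by 3.56 and 1.90, the splicing factors SRSF5 and SRSF11 by 3.86 and 3.48, and RNU6ATAC and RNU12 of the minor spliceosome by 6.60 and 5.72. MAT2A, which makes S-adenosylmethionine, rose from 5.71 ± 0.0283 to 36.5 ± 3.15 TPM, and the spermidine synthase gene SRM fell by 1.27. MYC stood at 22.9 ± 0.127 and 22.4 ± 0.962 TPM (adjusted p = 0.815). In total 10080 genes rose and 1110 fell for METTL3. After median-of-ratios scaling, 4711 rose and 5228 fell of 11642 tested, and METTL16 mRNA turned from 0.17 (adjusted p = 0.219) to -0.68.

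For METTL14 the same question gave a similar set of leading RNAs. RMRP rose from 274 ± 58.1 to 83857 ± 2625 TPM, 7SK from 483 ± 76.1 to 115992 ± 4695 and RPPH1 from 303 ± 64.2 to 61999 ± 3622, by 8.27, 7.91 and 7.69. SCARNA7, SCARNA5, SCARNA12, SCARNA10 and SCARNA28 rose by 8.36, 7.58, 7.52, 7.33 and 6.29, and SNAR-B1 and SNAR-B2 (identical rows) by 6.64. MIR3687-1 and MIR3687-2 (identical rows) were listed at 0 in input and at 630 ± 252 TPM in RIP. The largest falls were RNA5S9 (57.1 ± 19.1 to 0.410 ± 0.580 TPM), RNA28S5 (451 ± 36.9 to 11.04 ± 1.51), RNY4, RNY1, VTRNA1-1, MIR600 and VTRNA1-2, by 5.39, 5.23, 3.74, 3.06, 2.46, 2.30 and 2.18. SNORA100, MIR612 and MIR6720 were at 14.1 ± 0.0141, 6.65 ± 1.18 and 5.14 ± 0.665 TPM in input and listed at 0 in both RIPs. Adjusted p was 6.2e-04 or lower for all of these.

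Most lists rose nearly whole for METTL14, because the median gene did. Above the median gene, with their camera adjusted p, stood the m6A writer complex (8 of 8 rose, 1.19, 0.029, with METTL14 itself a member), nuclear long noncoding RNAs (11 of 11, 0.86, 0.033), replication-dependent histones (55 of 56, 0.98, 0.033), immediate early and stress genes (15 of 15, 1.01, 0.016), oxidative phosphorylation (75 of 76, 0.80, 0.0056), spliceosome protein genes (37 of 37, 0.79, 0.0058), proliferation genes (25 of 25, 0.49, 0.033), mitochondrial ribosomal proteins (76 of 77, 0.45, 0.029) and zinc finger genes (388 of 392, 0.06, 0.029). Without METTL3 and METTL14, a test chosen after seeing the data, the writer list lost that call (6 of 6 rose, 0.85, 0.134) and stood at 0.69 (0.349) for METTL3 and 0.71 (0.093) for METTL16. TERC, MALAT1 and NEAT1 rose by 6.16, 5.45 and 4.84, RBM15 by 4.06, WTAP from 2.19 ± 0.0212 to 21.4 ± 1.36 TPM, EGR1 from 0.735 ± 0.163 to 47.4 ± 2.16 TPM, HIST1H2AD and HIST2H2AC by 3.83 and 3.51, NDUFS5, ATP5J2 and COX7B by 3.89, 3.85 and 3.85, SRSF5 and SRSF11 by 4.74 and 4.17, CENPE and PCNA by 3.33 and 3.07, MRPL33 by 3.24 and ZNF121 by 3.89. Below it stood solute carriers (193 of 204 rose, -0.37, 0.0025) and the Pol III and RNP RNAs (5 of 13 rose, 7 fell, -2.74, 4.1e-40), the latter at 0.01 with quantile normalization. For small nucleolar and Cajal body RNAs (270 of 295 rose, 7 fell) the median stood 1.44 above that of all genes while camera, which weighs each gene by its spread, gave the opposite direction (0.040) and turned upward under median-of-ratios and quantile scaling. Cytosolic ribosomal proteins (71 of 79 rose, 3 fell) stood at -0.03 (downward, 2.4e-04) and spliceosomal snRNAs (11 of 15 rose) at 0.03 (downward, 0.0081), or -0.51 with median-of-ratios scaling. With an estimated correlation the call of the Pol III and RNP list held (adjusted p = 0.0035), and those of all other lists were lost (0.883 to 0.886). With median-of-ratios scaling calls were lost for spliceosome proteins (0.47, 0.065), proliferation genes (0.22, 0.182), mitochondrial ribosomal proteins (0.27, 0.130), spliceosomal snRNAs (0.654) and Pol III and RNP RNAs (-3.29, 0.599). Under it most members of some lists fell: 30 of 180 solute carriers rose and 123 fell, and 18 of 79 cytosolic ribosomal proteins rose and 53 fell.

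Lists not called for METTL14 were the snoRNA host genes (22 of 22 rose, 1.03, camera adjusted p = 0.072), m6A readers and erasers (16 of 16, 0.56, 0.212), the SAM and methionine cycle (15 of 17, 0.01, 0.057), translation initiation factors (39 of 40, 0.09, 0.985), ER chaperones (20 of 20, 0.11, 0.654), cholesterol biosynthesis (21 of 22, -0.06, 0.474) and reported m6A-bearing mRNAs (26 of 27, 0.01, 0.493). The medians of the SAM, initiation factor, chaperone and m6A-bearing lists turned below 0 with median-of-ratios scaling (-0.24, -0.31, -0.13 and -0.12). Under that scaling camera called the snoRNA host genes (0.82, adjusted p = 0.019). HNRNPA2B1 rose by 4.61, TAF1D by 4.02 and HSPA1A by 3.07. MAT2A rose from 4.43 ± 0.297 to 66.7 ± 6.55 TPM and MALAT1 from 5.21 ± 0.467 to 271 ± 13.5 TPM. MYC went from 16.8 ± 2.50 to 41.1 ± 0.912 TPM (1.25, adjusted p = 3.5e-07), which lay 0.13 below the median gene and turned to -0.63 after median-of-ratios scaling. In total 13003 genes rose and 76 fell for METTL14, against 4586 and 5141 after that scaling, where METTL16 mRNA turned from 0.90 to -0.75. The METTL14 inputs held 8518 and 8799 genes at 1 TPM or more, and its RIPs 13551 and 13695. Many genes therefore passed the filter through RIP libraries, which favours calls of a rise.

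For METTL16, 7SK rose most among RNAs above 0 in the input, from 271 to 235387 ± 413 TPM (9.76). SCARNA10, SCARNA5 and SCARNA7 rose by 8.16, 7.12 and 6.53, SNAR-B1 and SNAR-B2 (identical rows) by 7.67, RPPH1 from 283 to 39038 ± 3367 TPM (7.10) and TERC from 7.14 to 661 ± 67.5 TPM (6.34). MIR3687-1 and MIR3687-2 (identical rows), MIR6516 and SCARNA12 were listed at 0 in the input and at 1026 ± 106, 107 ± 44.3 and 92.1 ± 27.1 TPM in RIP. The largest falls were the U1 snRNA copies RNU1-1, RNU1-2, RNU1-3, RNU1-4 and RNVU1-18, whose 5 rows were identical (60.04 to 6.60 ± 0.948 TPM, -3.01), MIR6720 (-2.49), RNA28S5 (58.4 to 9.84 ± 1.09 TPM, -2.46), UPK3BL (-2.28) and the box C/D snoRNAs SNORD29 and SNORD33 (-2.12 and -2.08). Adjusted p was 0.0024 or lower for all of these. U6 snRNA (RNU6-1) did not pass the filter and was not tested. MAT2A (chromosome 2, 85539168 to 85545281) rose from 2.28 to 62.8 ± 24.5 TPM, by 4.23 ± 0.24 (SE, adjusted p = 3.7e-08). Among the 11639 protein-coding genes tested its difference was exceeded, METTL16 apart, by RPL21 (8.90 to 205 ± 57.5 TPM, 4.35), a ranking chosen after the values were seen. After median-of-ratios scaling 17 protein-coding genes lay above MAT2A (2.61). With the 4 METTL3 and METTL14 inputs as the reference MAT2A rose by 3.35 and none lay above it.

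Lists called above the median gene for METTL16 were, with camera adjusted p, oxidative phosphorylation (74 of 76 rose, 1.13, 2.7e-07), proliferation genes (25 of 25, 1.00, 1.2e-04), spliceosome protein genes (37 of 37, 0.99, 1.9e-05), replication-dependent histones (53 of 56, 0.94, 0.0025), cytosolic ribosomal proteins (73 of 79 rose, 1 fell, 0.93, 0.0065), nuclear long noncoding RNAs (11 of 11, 0.92, 0.0065), snoRNA host genes (22 of 22, 0.83, 0.013), ER chaperones (20 of 20, 0.79, 0.0087), translation initiation factors (39 of 40, 0.74, 5.1e-04), m6A readers and erasers (16 of 16, 0.68, 0.0070) and mitochondrial ribosomal proteins (75 of 77, 0.61, 1.7e-04). COX7C, COX7B and NDUFB1 rose by 3.75, 3.70 and 3.37, RPL21, RPL30 and RPL36A by 4.35, 3.55 and 3.48, EIF3E by 3.09, HSP90B1 by 3.06, PCNA by 2.95, SNRPE and SNRPG by 3.23 and 2.99, HIST1H2AD by 3.06, HNRNPA2B1 by 4.05, SNHG6 by 3.17, MRPL51 by 3.03, MALAT1 from 2.46 to 138 ± 27.0 TPM and NEAT1 by 4.36. Solute carriers (156 of 204 rose, 7 fell) stood at -0.26 (0.0016). Spliceosomal snRNAs (9 of 15 rose, 5 fell) stood at 0.60, while camera gave the opposite direction (5.1e-04), and so did small nucleolar and Cajal body RNAs (233 of 295 rose, 8 fell, 0.69, 0.044). RNU5E-1, RNU6ATAC and RNU12 rose by 6.13, 6.31 and 4.03. All these calls were lost with an estimated correlation (adjusted p = 0.798). With the 4 METTL3 and METTL14 inputs in place of the METTL16 input, cytosolic ribosomal proteins turned to -0.08 (camera adjusted p = 0.773) and spliceosomal snRNAs to -0.09 (0.934). Calls were also lost for initiation factors (0.05, 0.934), proliferation genes (0.33, 0.171), spliceosome proteins (0.31, 0.297), ER chaperones (0.23, 0.655), m6A readers (0.31, 0.353) and mitochondrial ribosomal proteins (0.18, 0.326). Calls kept with these inputs were those of oxidative phosphorylation (0.65, 0.0058), nuclear long noncoding RNAs (0.58, 0.011), histones (0.52, 0.0015), snoRNA host genes (0.48, 0.041) and solute carriers (-0.28, 0.0050), and small nucleolar RNAs stood at 1.53 (upward, 5.7e-13). With median-of-ratios scaling the medians of ribosomal proteins and snRNAs also turned (-0.13 and -0.51, adjusted p = 0.939 and 0.781). Of 79 cytosolic ribosomal proteins 35 then rose and 36 fell, and of 180 solute carriers 45 rose and 115 fell. Histones (0.11, 0.735), initiation factors (0.16, 0.525), ER chaperones (0.56, 0.354), m6A readers (0.57, 0.173), spliceosome proteins (0.41, 0.173), mitochondrial ribosomal proteins (0.33, 0.169) and proliferation genes (0.52, 0.053) lost their calls under that scaling. Oxidative phosphorylation (0.66, 0.037), nuclear long noncoding RNAs (0.92, 0.042), snoRNA host genes (0.76, 0.048) and solute carriers (-0.47, 0.0085) kept theirs under both, and small nucleolar RNAs stood at 0.56 (upward, 0.048).

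Lists not called for METTL16 were the m6A writer complex (8 of 8 rose, 0.71, camera adjusted p = 0.056), immediate early and stress genes (15 of 15, 0.47, 0.141), the SAM and methionine cycle (15 of 17, 0.46, 0.417), cholesterol biosynthesis (20 of 22, 0.27, 0.401), reported m6A-bearing mRNAs (25 of 27, -0.01, 0.862), zinc finger genes (349 of 392, -0.13, 0.977) and the Pol III and RNP RNAs (8 of 13 rose, 1 fell, -0.16, 0.217). Median-of-ratios scaling turned the SAM, cholesterol and zinc finger lists to -0.13, -0.27 and 0.32. WTAP went from 0.210 to 5.28 ± 0.905 TPM. MYC went from 7.07 to 9.35 ± 0.997 TPM (0.35, adjusted p = 0.037), 0.52 below the median gene, and to -1.51 after median-of-ratios scaling. In total 11676 genes rose and 116 fell for METTL16. The counts were 4880 and 5067 after median-of-ratios scaling, 7751 and 1919 without spike-ins, and 6876 and 3262 against the 4 other inputs. Without METTL16 RIP replicate 1 the falls numbered 192. Adjusted over the list alone, counts in the 3 RIP comparisons were the same except for small nucleolar RNAs (269 rose), snoRNA host genes (21 rose), ribosomal proteins (21 fell), mitochondrial ribosomal proteins (6 fell), zinc finger genes (333 rose, 17 fell), solute carriers (117 rose, 31 fell) and m6A-bearing mRNAs (23 rose) for METTL3, and ribosomal proteins (2 fell) and solute carriers (153 rose, 6 fell) for METTL16.

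**Figure D3:**
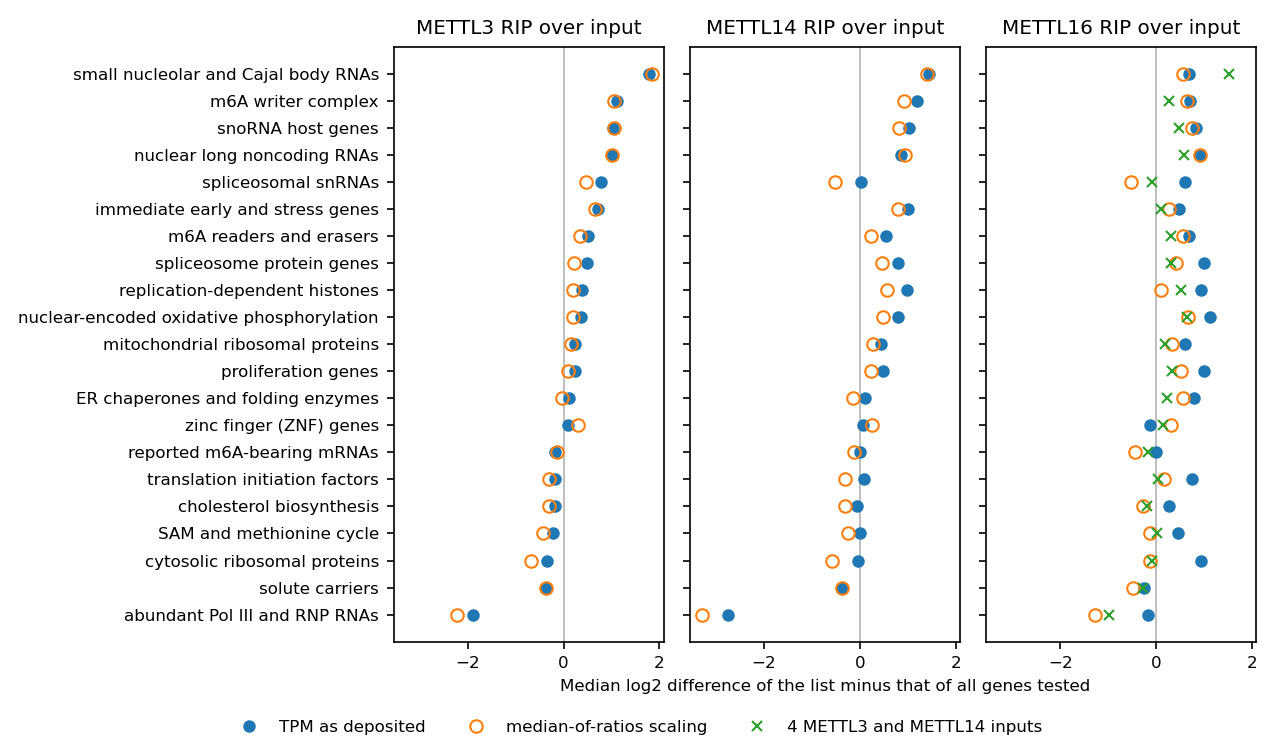
Median log2 difference of each of the 21 lists tested minus the median of all genes, for the 3 RIP over input comparisons; filled points are TPM as deposited, open points median-of-ratios scaling, and crosses METTL16 RIP against the METTL3 and METTL14 inputs. Cytosolic ribosomal proteins moved from 0.93 to -0.08 for METTL16 when the other inputs were used.

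Which RNAs the proteins shared was asked next. Of 13486 genes tested, 9504 rose and 30 fell in all 3 comparisons, against 3279 and 3872 of 11642 after median-of-ratios scaling. METTL3 and METTL14 shared 10049 risen genes where independent lists would share 9719 (odds ratio 49.6, 95% interval 34.4 to 74.0, Fisher's exact test), METTL3 and METTL16 shared 9508 against 8727 (9.49, 8.497 to 10.6), and METTL14 and METTL16 shared 11570 against 11258 (28.7, 22.9 to 36.2). Fallen genes shared numbered 73, 95 and 30 against 6.26, 9.55 and 0.654. With median-of-ratios scaling the odds ratios of risen genes were 146, 15.8 and 10.99, so the order of the METTL16 pairs turned, and shared fallen genes numbered 4769, 4159 and 3941 against 2309, 2275 and 2238. Each protein has its own inputs, so no library is shared, but the calls share 1 gene-wise spread in the fit, which can raise these overlaps. Genes at least 2-fold higher in every RIP library than in every input library do not use that spread. Of these, the pairs in the same order shared 3444, 2456 and 4560 against 2358, 1287 and 3378, with odds ratios of 72.4, 7.09 and 9.18. Across genes, which are not independent replicates, log2 differences correlated at r = 0.934 (METTL3 and METTL14), 0.657 (METTL3 and METTL16) and 0.681 (METTL14 and METTL16). Median-of-ratios scaling gave 0.962, 0.786 and 0.756. Against the 4 METTL3 and METTL14 inputs the METTL16 pairs stood at 0.854 and 0.767 and their odds ratios at 47.4 and 24.5, but the comparisons then share inputs, which raises such values by construction. The correlations of the METTL16 pairs stayed below that of METTL3 and METTL14 in each of these settings. The order of the METTL16 pairs turned with median-of-ratios scaling and against the 4 other inputs. It also turned without spike-ins, small RNAs and overexpressed genes, at 0.734 (METTL3 and METTL16) and 0.695 (METTL14 and METTL16).

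**Figure D4:**
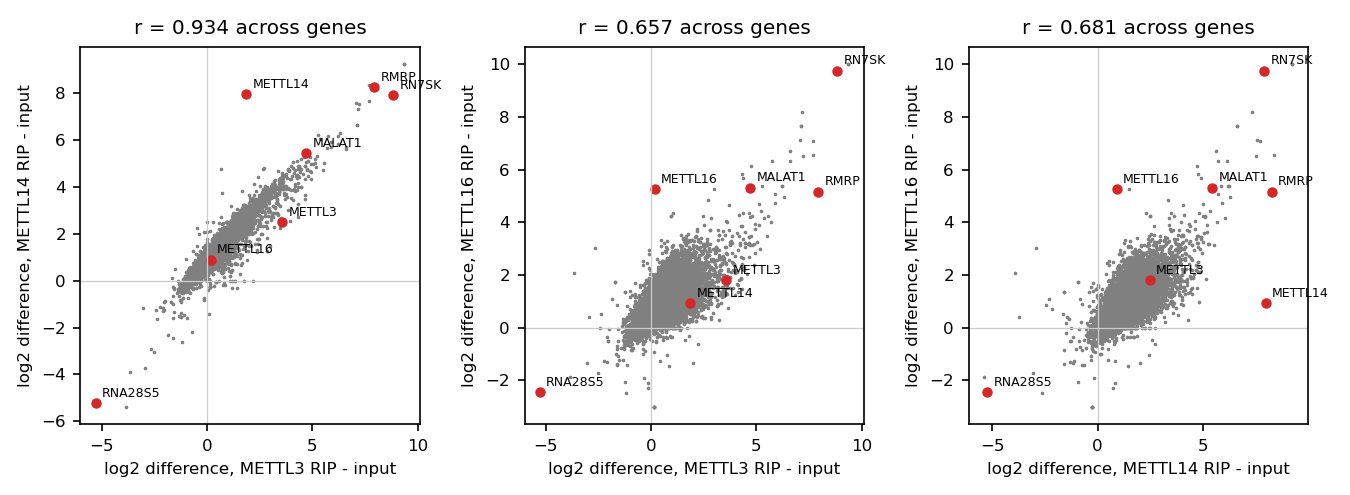
log2 differences between RIP and input of 13486 genes for each pair of proteins, with selected genes in red. r was 0.934 between METTL3 and METTL14, 0.657 between METTL3 and METTL16, and 0.681 between METTL14 and METTL16.

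The difference between METTL14 and METTL3 was tested directly. The immediate early gene EGR1 rose more with METTL14 (27.1 ± 2.96 TPM in METTL3 RIP and 47.4 ± 2.16 in METTL14 RIP, from inputs of 3.29 ± 0.0990 and 0.735 ± 0.163), by 2.10 more on the log2 scale (adjusted p = 1.4e-04). Relative to the median gene that was 1.36. EGR1 was higher in the METTL3 inputs than in the METTL14 inputs, so part of this difference lies in the inputs. SNORD139, MIR7111, MIR4745, MIR4292 and MIR6741 were also higher, the last 3 listed at 0 in all 4 inputs. RNY5, SNORD50B (listed at 0 in all 4 inputs), RNA5S9, MIR4521, VTRNA1-2 and SNORD54 were lowest. The median gene differed by 0.74, and 12734 genes were higher and 44 lower, but 223 and 172 after median-of-ratios scaling and 33 and 50 after quantile normalization. Relative to the median gene MAT2A stood at 0.42, WTAP at 0.27, MYC at 0.54 and 7SK at -1.66. Below the median gene for METTL14 stood the Pol III and RNP RNAs (-0.91, camera adjusted p = 2.7e-54), spliceosomal snRNAs (-1.01, 9.2e-53) and small nucleolar and Cajal body RNAs (-0.49, 1.4e-168), and these calls held with an estimated correlation (adjusted p = 0.0017, 0.018 and 0.012). Of the 295 small nucleolar RNAs 58 were called higher and 14 lower, or 15 and 3 adjusted over the list alone. Replication-dependent histones (0.56, 0.015), oxidative phosphorylation (0.38, 8.0e-08), ribosomal proteins (0.34, 0.032), spliceosome protein genes (0.27, 0.0050), mitochondrial ribosomal proteins (0.22, 0.0043) and proliferation genes (0.21, 0.0059) stood above it, and snoRNA host genes at -0.04 (0.024), all with adjusted p = 0.926 with an estimated correlation.

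METTL16 and METTL3 differed in 6883 genes, 5189 higher and 1694 lower for METTL16, around a median of 0.26. The split hung on the scaling and the input: 3515 higher and 3653 lower after median-of-ratios scaling, 741 and 4296 without spike-ins (median -0.25), and 211 and 9546 against the other inputs (median -0.48). RPL21 rose 3.29 more with METTL16 (adjusted p = 1.9e-05). RNY4 differed by 3.36 (-2.97 with METTL3, and 0.39 with METTL16 at adjusted p = 0.135), and SNORD141A and SNORD141B (identical rows) by 3.45. SNORA100 and MIR612 were highest, listed at 0 in both METTL3 RIPs. SNORD36C and the 5 U1 copies were lowest. MAT2A rose 1.75 more with METTL16 (adjusted p = 9.5e-04), or 0.87 more (0.0041) against the other inputs and 0.85 more (0.051) without spike-ins. MYC (0.39), MALAT1 (0.60), WTAP (0.57) and 7SK (0.92) had adjusted p of 0.106, 0.036, 0.017 and 0.0079, and after median-of-ratios scaling stood at -0.49, -0.08, 0.89 and -0.04. Against the other inputs WTAP turned to -0.98. Ribosomal proteins stood 1.22 above the median gene (77 of 79 called higher, 78 adjusted over the list alone, camera adjusted p = 2.9e-17), initiation factors 0.70 (31 of 40 called higher, 4.2e-06), ER chaperones 0.71 (1.3e-04), oxidative phosphorylation 0.67 (4.3e-08), proliferation genes 0.58 (2.0e-04), cholesterol biosynthesis 0.58 (9.6e-04), the SAM and methionine cycle 0.52 (4.4e-04), spliceosome proteins 0.46 (0.012), m6A readers 0.40 (0.038), histones 0.39 (0.0065) and mitochondrial ribosomal proteins 0.31 (0.0012). Spliceosomal snRNAs stood at -1.39 (1.3e-05), small nucleolar RNAs at -1.20 (1.2e-23), stress genes at -0.38 (0.044) and zinc finger genes at -0.25 (2.0e-04). All were lost with an estimated correlation (adjusted p = 0.714). With the 4 other inputs ribosomal proteins stood at 0.41 (1.3e-21), oxidative phosphorylation at 0.15 (0.015), histones at 0.12 (0.011), initiation factors at 0.08 (0.034) and stress genes at -0.38 (0.011). Calls were lost for ER chaperones (0.08, 0.096), the SAM and methionine cycle (0.08, 0.052), proliferation genes (0.10, 0.754), cholesterol biosynthesis (0.16, 0.227), zinc finger genes (-0.02, 0.227) and spliceosomal snRNAs (-0.83, 0.227), and m6A readers, mitochondrial ribosomal proteins and spliceosome proteins turned to -0.04, -0.05 and -0.04. Small nucleolar RNAs stood at -0.29 there, with camera upward (2.5e-04). With median-of-ratios scaling histones turned to -0.15 (0.641), and calls were lost for m6A readers (0.19, 0.186), the SAM and methionine cycle (0.18, 0.098), cholesterol biosynthesis (0.29, 0.074), zinc finger genes (-0.09, 0.056), stress genes (-0.59, 0.099) and spliceosome proteins (0.07, 0.574).

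METTL16 and METTL14 differed in 8212 genes, 685 higher and 7527 lower for METTL16 around a median of -0.49, and 3653 higher and 4161 lower after median-of-ratios scaling. Without spike-ins 85 were higher and 11755 lower, and against the other inputs 55 and 13081. EGR1 was 3.85 lower for METTL16 (1.26 ± 0.467 TPM in METTL16 RIP, adjusted p = 7.6e-07), and SNORD86, SNORD58C, SNORD36C, SNORD70 and MIR4292 were also lowest. RNY4 (4.13), RNA5S9 (3.52), MIR4521 and MIR600 were among the highest, with SNORA100 and MIR612. 7SK was 1.84 higher and MYC 0.90 lower for METTL16 (differences of 1.84 and -0.90, adjusted p = 7.1e-05 and 0.0016). MAT2A (0.59), MALAT1 (-0.14) and WTAP (-0.44) had adjusted p of 0.123, 0.583 and 0.046, and after median-of-ratios scaling stood at 0.82, 0.11 and 0.72. Pol III and RNP RNAs stood 2.16 above the median gene (camera adjusted p = 4.2e-13, and 0.052 with an estimated correlation). Ribosomal proteins stood at 0.85 (32 of 79 called higher and 4 lower, 1.2e-25), ER chaperones at 0.56 (1.0e-04), initiation factors at 0.53 (13 of 40 called higher and 9 lower, 1.4e-07), cholesterol biosynthesis at 0.45 (0.014), proliferation genes at 0.31 (0.012), the SAM and methionine cycle at 0.24 (0.0034) and oxidative phosphorylation at 0.23 (0.0089), with zinc finger genes at -0.17 (1.0e-04) and stress genes at -0.65 (0.015). These were lost with an estimated correlation (adjusted p = 0.968). With the 4 other inputs ribosomal proteins stood at 0.08 (camera adjusted p = 2.8e-04) and initiation factors, chaperones, oxidative phosphorylation and proliferation genes at -0.08, -0.17, -0.25 and -0.23. The SAM, cholesterol and zinc finger lists stood at -0.12, -0.10 and 0.03, while Pol III and RNP RNAs (1.83, 5.5e-76) and stress genes (-0.77, 0.020) kept their calls. With median-of-ratios scaling the calls of ribosomal proteins (0.39, 2.5e-04) and initiation factors (0.41, 0.010) were kept. Those of Pol III and RNP RNAs (1.69, 0.054), ER chaperones (0.39, 0.054), stress genes (-0.73, 0.054), proliferation genes (0.33, 0.075), zinc finger genes (-0.10, 0.155), oxidative phosphorylation (0.14, 0.274), the SAM and methionine cycle (0.19, 0.274) and cholesterol biosynthesis (0.25, 0.298) were lost.

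The tables list no mitochondrially encoded genes, so those lists had no members. Of 20 markers of blood, liver, stromal and endothelial cells, 18 lay below the filter and the highest value was 3.01 TPM (COL1A1).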

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

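The tests of the nuclear long noncoding RNAs, of the overexpressed transcripts, of the initiation factors and of ribosomal proteins against METTL14 were chosen after their results were seen, and those of ribosomal proteins against METTL3 before.

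Genes whose difference between RIP and input was not the same for 2 proteins drew a closer look. They numbered 12778 for METTL14 against METTL3, 6883 for METTL16 against METTL3 and 8212 for METTL16 against METTL14. The median gene itself differed by 0.74, 0.26 and -0.49, and after median-of-ratios scaling the counts were 395, 7168 and 7814. For METTL16 against METTL3 the split went from 5189 higher and 1694 lower to 741 and 4296 without spike-ins. For METTL14 minus METTL3 the highest were SNORD139 (4.09), MIR4745 (3.03), MIR4292 (2.15), MIR7111 (2.10), EGR1 (2.10) and MIR6741 (2.06), and the lowest RNY5 (-1.64), SNORD50B (-1.57), RNA5S9 (-1.52), MIR4521 (-1.52), VTRNA1-2 (-1.48) and SNORD54 (-1.43). Part of the EGR1 difference lies in the inputs, where EGR1 was higher for METTL3. The METTL3 transcript stood at -1.08 and the METTL14 transcript at 6.11. The Pol III and RNP RNAs (-0.91), spliceosomal snRNAs (-1.01) and small nucleolar RNAs (-0.49) were the lists with a difference that an estimated correlation kept.

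For METTL16 minus METTL3 the highest were SNORA100 (5.75), MIR612 (5.69), SNORD141A and SNORD141B (3.45, identical values), RNY4 (3.36) and RPL21 (3.29). The lowest were SNORD36C (-3.31) and RNU1-1, RNU1-2, RNU1-3, RNU1-4 and RNVU1-18 (-3.15, identical values), with the METTL3 transcript at -1.77 and the METTL16 transcript at 5.09. For METTL16 minus METTL14 they were SNORA100 (5.99), MIR612 (5.95), RNY4 (4.13), MIR4521 (3.78), RNA5S9 (3.52) and MIR600 (3.38), against SNORD86 (-4.01), EGR1 (-3.85), SNORD58C (-3.50), MIR4292 (-3.34), SNORD36C (-3.33) and SNORD70 (-3.32). There the METTL14 transcript stood at -7.05 and the METTL16 transcript at 4.36. Differences of genes listed at 0 in a group depend on the pseudocount.

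The 11 listed nuclear long noncoding RNAs were higher over input in all 3 RIPs. All 675 lncRNAs tested had medians of 0.16 (METTL3), 0.0033 (METTL14) and -0.27 (METTL16) relative to the median gene, so the class did not stand as high. A change of makeup moves all genes of a library by 1 factor, which by itself leaves a list near the median gene, apart from the pseudocount and the filter. This list's median stood 1.00, 0.86 and 0.92 above the median gene. Median-of-ratios scaling brought the median gene to -0.04, -0.03 and -0.01, with the list 1.00, 0.94 and 0.92 above it (camera adjusted p = 0.0086, 0.012 and 0.042). Makeup is therefore not the whole cause for the listed members' median. That scaling also applies 1 factor per library. It can move these values only through the pseudocount and the filter, and is no separate test. After it 8, 8 and 9 of the 11 members were called higher and 1, 1 and 2 lower. The list stood at 0.831 or more in each of 10 pairs of RIP and input library (SD up to 0.102), but the pairs reuse libraries. An estimated correlation, run without that scaling, ended the list's calls (0.915, 0.883 and 0.798). For nuclear long noncoding RNAs beyond those listed a change of makeup stays open, since the lower 95% limit of the median over the 11 members reached -0.39. A low recovery of nuclear RNA in the inputs could give the same rise with all proteins, since the list's relative medians lay within 0.141 of each other. Binding by these nuclear proteins could also give it, with a lowest relative median of 0.861, and a control precipitation, not used here, would help to separate these.

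Ribosomal protein and translation factor mRNAs stood higher relative to the median gene with METTL16 than with METTL3 or METTL14, though against METTL14 only 32 of 79 and 13 of 40 were called higher, and an estimated correlation ended the list calls (adjusted p = 0.714 and 0.968). Abundance is not the whole cause for ribosomal proteins against METTL3: the list's median of 1.48 lay at percentile 100 of 1000 lists matched on abundance, which ranged from 0.78 to 1.17. Those matched lists themselves lay above the median of all genes (0.26), so abundance may account for part of the difference. With the 4 other inputs the relative medians were 0.0763 (initiation factors against METTL3), -0.0799 (initiation factors against METTL14) and 0.0755 (ribosomal proteins against METTL14), under the 0.3 that the single METTL16 input as a cause calls for, so that library may account for these. Ribosomal proteins against METTL3 stood at 0.409 with those inputs and at 0.583 with median-of-ratios scaling, between the values set in advance for and against (0.3 and 0.6), so the input and its scaling stay open there. A second METTL16 input, not used here, would test this.

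Each overexpressed transcript was higher in the RIP of its own protein. Genes of the same input abundance did not rise as far, since the lowest of the 3 percentiles was 100. They numbered 26 (METTL3), 603 (METTL14) and 364 (METTL16), with highest differences of 1.02, 3.44 and 4.35. The 26 genes had a median of -0.26 and are too few for a fine percentile. A property of the expressed transcript stays open: the smallest gap to another protein's RIP was 1.79 log2 units, but the own inputs held 2.02 to 79.5 times the highest other input, so the other RIPs need not hold that transcript. Capture of the mRNA with the tagged protein as it is made was not tested.

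Spike-ins were left out of the test, and the share they held in the METTL16 input (55.9% of TPM) drew attention. The 71 spike-ins above 0 in all libraries correlated between that input and the other libraries at 0.994 to 0.998.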

How the results depend on the processing

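Each result was fitted again under the alternatives, and those that turned or whose counts moved by over 1.5 times are given here. A list or gene turned where the direction of its test changed and it passed in at least 1 of the settings. The value in brackets is the relative median of a list, or the log2 difference of a gene, under that alternative. camera weighs each gene by its spread, so a test can turn while the median keeps its sign. Where no cause follows from the construction, the cause was not tested.

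With a pseudocount of 0.1, genes that turned for METTL16 minus METTL14 were WTAP (0.88). With a pseudocount of 5, the METTL14 minus METTL3 test turned for cytosolic ribosomal proteins (0.59). Lists that turned for METTL16 minus METTL14 were small nucleolar and Cajal body RNAs (-0.37). Turned genes of METTL16 minus METTL3 were WTAP (-0.18). Without a filter on low values, gene counts in RIP over input were 117 lower for METTL14 and 238 lower for METTL16. For METTL14, the lists that turned were small nucleolar and Cajal body RNAs (1.80), cytosolic ribosomal proteins (0.54) and translation initiation factors (0.69). Among lists, METTL16 turned for small nucleolar and Cajal body RNAs (1.10) and zinc finger genes (0.26). Turned lists of METTL14 minus METTL3 were snoRNA host genes (0.18). With the filter at 5 TPM, gene counts in RIP over input were 6102 higher for METTL3, 8052 higher for METTL14 and 7528 higher for METTL16. Genes that differed between proteins numbered 8115 between METTL14 and METTL3 and 4811 between METTL16 and METTL14. In METTL14, camera turned for small nucleolar and Cajal body RNAs (1.57). The METTL16 test turned for small nucleolar and Cajal body RNAs (0.66). At a threshold of 2-fold, gene counts in RIP over input were 4160 higher and 110 lower for METTL3, 25 lower for METTL14 and 5759 higher and 24 lower for METTL16. Genes that differed between proteins numbered 2038 between METTL14 and METTL3, 1770 between METTL16 and METTL3 and 2349 between METTL16 and METTL14. With each table fitted alone, gene counts in RIP over input were 7692 higher and 31 lower for METTL16. A stricter filter or threshold leaves fewer genes by construction.

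Under median-of-ratios scaling, gene counts in RIP over input were 4711 higher and 5228 lower for METTL3, 4586 higher and 5141 lower for METTL14 and 4880 higher and 5067 lower for METTL16. Differences between proteins were called in this many genes: 395 between METTL14 and METTL3. Lists that turned for METTL14 were spliceosomal snRNAs (-0.51) and small nucleolar and Cajal body RNAs (1.39). For METTL16, the lists that turned were small nucleolar and Cajal body RNAs (0.56) and cytosolic ribosomal proteins (-0.13). Among lists, METTL16 minus METTL3 turned for replication-dependent histones (-0.15) and reported m6A-bearing mRNAs (-0.26). The METTL3 difference turned for the transcripts METTL16 (-0.68). Among genes, METTL14 turned for METTL16 (-0.75) and MYC (-0.63). For METTL16 the genes that turned were MYC (-1.51). Genes that turned for METTL14 minus METTL3 were METTL16 (-0.065) and MALAT1 (-0.19). Turned genes of METTL16 minus METTL3 were MALAT1 (-0.076), MYC (-0.49) and RN7SK (-0.036). The METTL16 minus METTL14 difference turned for the transcripts WTAP (0.72). That scaling sets the median difference near 0 by construction, so counts of rises and falls become similar.

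Under quantile normalization, gene counts in RIP over input were 4704 higher and 5871 lower for METTL3, 4622 higher and 5836 lower for METTL14 and 4886 higher and 5495 lower for METTL16. Genes that differed between proteins numbered 83 between METTL14 and METTL3. Turned lists of METTL3 were abundant Pol III and RNP RNAs (0.011). In METTL14, camera turned for abundant Pol III and RNP RNAs (0.0076), spliceosomal snRNAs (0.39) and small nucleolar and Cajal body RNAs (1.34). The METTL16 test turned for small nucleolar and Cajal body RNAs (0.64). Lists that turned for METTL16 minus METTL3 were replication-dependent histones (-0.16) and reported m6A-bearing mRNAs (-0.23). For METTL16 minus METTL14, the lists that turned were spliceosomal snRNAs (-1.24). Among genes, METTL3 turned for METTL16 (-0.53). For METTL14 the genes that turned were METTL16 (-0.65) and MYC (-0.20). Genes that turned for METTL16 were MYC (-0.79). Turned genes of METTL14 minus METTL3 were METTL16 (-0.12). The METTL16 minus METTL3 difference turned for the transcripts MALAT1 (-0.070) and MYC (-0.30). Among genes, METTL16 minus METTL14 turned for WTAP (0.45).

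Rescaled without small RNAs and overexpressed genes, gene counts in RIP over input were 2230 lower for METTL3, 1830 lower for METTL14 and 2 lower for METTL16. Differences between proteins were called in this many genes: 31 between METTL14 and METTL3, 13351 between METTL16 and METTL3 and 13319 between METTL16 and METTL14. Among lists, METTL16 turned for replication-dependent histones (1.36), solute carriers (-0.26) and reported m6A-bearing mRNAs (0.30). Turned lists of METTL16 minus METTL3 were zinc finger genes (-0.51) and immediate early and stress genes (0.36). In METTL16 minus METTL14, camera turned for zinc finger genes (-0.50) and reported m6A-bearing mRNAs (0.30). For METTL16 the genes that turned were UPK3BL (0.083). Genes that turned for METTL14 minus METTL3 were MALAT1 (-0.18). Turned genes of METTL16 minus METTL14 were WTAP (3.35), MALAT1 (3.65) and MYC (2.84). The spike-ins stay in this rescaling, and they take most of what remains of the METTL16 input, which lifts nearly all METTL16 differences by construction.

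The next settings were chosen after seeing the data. Rescaled without spike-ins, gene counts in RIP over input were 7751 higher and 1919 lower for METTL16. The METTL16 test turned for small nucleolar and Cajal body RNAs (0.53). Lists that turned for METTL16 minus METTL3 were replication-dependent histones (-0.14). For METTL16 minus METTL14, the lists that turned were small nucleolar and Cajal body RNAs (-0.80) and nuclear-encoded oxidative phosphorylation (-0.087). The METTL16 difference turned for the transcripts MYC (-0.71). Among genes, METTL16 minus METTL3 turned for MALAT1 (-0.31), MYC (-0.67) and RN7SK (-0.23). Rescaled without spike-ins, small RNAs and overexpressed genes, gene counts in RIP over input were 3046 lower for METTL3, 3066 lower for METTL14 and 3943 lower for METTL16. Differences between proteins were called in this many genes: 227 between METTL14 and METTL3. Among lists, METTL16 turned for cytosolic ribosomal proteins (-0.30). Turned lists of METTL16 minus METTL3 were replication-dependent histones (-0.13) and reported m6A-bearing mRNAs (-0.29). For METTL14 the genes that turned were MYC (-0.16). Genes that turned for METTL16 were MYC (-1.08). Turned genes of METTL14 minus METTL3 were MALAT1 (-0.30). The METTL16 minus METTL3 difference turned for the transcripts MALAT1 (-0.23) and MYC (-0.61). Among genes, METTL16 minus METTL14 turned for WTAP (1.204). Against the 4 METTL3 and METTL14 inputs, gene counts in RIP over input were 6876 higher and 3262 lower for METTL16. Genes that differed between proteins numbered 13136 between METTL16 and METTL14. In METTL16, camera turned for spliceosomal snRNAs (-0.087), small nucleolar and Cajal body RNAs (1.53) and cytosolic ribosomal proteins (-0.081). The METTL16 minus METTL3 test turned for m6A readers and erasers (-0.037), small nucleolar and Cajal body RNAs (-0.29), mitochondrial ribosomal proteins (-0.047) and spliceosome protein genes (-0.037). Lists that turned for METTL16 minus METTL14 were small nucleolar and Cajal body RNAs (0.30), nuclear-encoded oxidative phosphorylation (-0.25), cholesterol biosynthesis (-0.10), proliferation genes (-0.23) and spliceosome protein genes (-0.44). For METTL16 the genes that turned were METTL3 (-2.76), METTL14 (-1.24) and MYC (-0.99). Genes that turned for METTL16 minus METTL3 were WTAP (-0.98), MALAT1 (-0.17) and MYC (-0.96). Overexpression of METTL3 and METTL14 raised their own transcripts in those inputs, so the fall of the METTL3 and METTL14 transcripts follows from the construction.

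With the replicate block, for METTL3, the lists that turned were abundant Pol III and RNP RNAs (-1.89). Among lists, METTL14 turned for spliceosomal snRNAs (0.029) and small nucleolar and Cajal body RNAs (1.44). Turned lists of METTL16 were abundant Pol III and RNP RNAs (-0.16), spliceosomal snRNAs (0.60) and small nucleolar and Cajal body RNAs (0.69). Gene counts with the replicate block were 9869 higher and 937 lower (METTL3), 12990 and 76 (METTL14), 11404 and 102 (METTL16), and 12911, 6019 and 7403 for the differences between METTL14 and METTL3, METTL16 and METTL3, and METTL16 and METTL14. RIP and input deviations with the same number correlated at 0.0686 for METTL3 and 0.0138 for METTL14, so such libraries shared little gene-wise deviation. The sample titles number RIP and input alike. Whether libraries of the same number came from the same cells cannot be told from these values.

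fry tests a list against 0, not against all other genes, so a list whose median lies between 0 and that of all genes can turn by construction. The value in brackets is the list's median itself. Among the turns this does not cover is the Pol III and RNP list for METTL3 and METTL14, with a median below 0. Others are small nucleolar RNAs and spliceosomal snRNAs for METTL14 and METTL16, whose medians lay above that of all genes. With fry, the METTL3 test turned for SAM and methionine cycle (0.44), abundant Pol III and RNP RNAs (-1.22), cytosolic ribosomal proteins (0.32), translation initiation factors (0.51), cholesterol biosynthesis (0.50), solute carriers (0.32) and reported m6A-bearing mRNAs (0.51). Turned in METTL14 were SAM and methionine cycle (1.39), abundant Pol III and RNP RNAs (-1.36), spliceosomal snRNAs (1.41), small nucleolar and Cajal body RNAs (2.82), cytosolic ribosomal proteins (1.35), translation initiation factors (1.47), cholesterol biosynthesis (1.32) and solute carriers (1.01). The METTL16 test turned for abundant Pol III and RNP RNAs (0.71), spliceosomal snRNAs (1.47), small nucleolar and Cajal body RNAs (1.56), zinc finger genes (0.74), solute carriers (0.62) and reported m6A-bearing mRNAs (0.87). Turned in METTL14 minus METTL3 were nuclear long noncoding RNAs (0.64), small nucleolar and Cajal body RNAs (0.25), snoRNA host genes (0.70) and solute carriers (0.69). The METTL16 minus METTL14 test turned for SAM and methionine cycle (-0.26), nuclear-encoded oxidative phosphorylation (-0.26), cholesterol biosynthesis (-0.041) and proliferation genes (-0.18).

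Leaving out each library in turn (10 fits) gave 9204 to 10336 higher and 809 to 1268 lower genes for METTL3, 11805 to 13036 higher and 56 to 89 lower genes for METTL14 and 10896 to 12041 higher and 90 to 192 lower genes for METTL16. The 192 lower genes of METTL16 came without METTL16 RIP replicate 1. Differences between proteins ranged over 11518 to 12869 (METTL14 and METTL3), 5354 to 8096 (METTL16 and METTL3) and 6334 to 9537 (METTL16 and METTL14). Odds ratios of the overlaps of risen genes ranged over 38.1 to 66.9 (METTL3 and METTL14), 8.64 to 13.5 (METTL3 and METTL16) and 24.4 to 30.8 (METTL14 and METTL16). Other settings moved these odds ratios further. In the same order they were 89.3, 3.77 and 3.55 when rescaled without small RNAs and overexpressed genes, and 412, 23.9 and 34.4 with each table fitted alone. For METTL14 the small nucleolar and Cajal body RNAs' relative median ranged from 1.29 to 1.55 and its test turned in the fits without METTL14 RIP replicate 1 (1.29) and without METTL14 RIP replicate 2 (1.55).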

Other observations

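The test of gene span over the 3 proteins was written down before its result was seen, and those for METTL3 and METTL16 alone and the ranking of protein-coding genes below were chosen after.

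Apart from the METTL3, METTL14 and METTL16 transcripts, left out of this ranking, the protein-coding genes that rose most with METTL3 and METTL14 were largely the same. LUC7L3 rose by 4.61 and 5.26 (METTL3 and METTL14) and CCNL2 by 4.26 and 5.13. GOLGA8A (4.08 and 4.81), AGAP9 (3.96 and 4.88), CCDC14 (3.89 and 4.66), ANKRD36 (3.88 and 4.71) and SRSF5 (3.86 and 4.74) followed, with COX20 (3.79) for METTL3 and EGR1 (4.80) for METTL14. With METTL16 the highest after RPL21 and MAT2A were SUMO2 (4.14), HNRNPA2B1 (4.05), LSM3 (3.91), COX7C (3.75), RPL36AL (3.70) and COX7B (3.70). CCNL2, ANKRD36 and PILRB were 2.42, 2.36 and 2.30 lower for METTL16 than for METTL3 (differences of -2.42, -2.36 and -2.30). AMD1, whose product makes decarboxylated S-adenosylmethionine for polyamines, was 1.89 higher for METTL16 than for METTL14 and 2.46 higher than for METTL3.

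Some protein-coding genes fell or stayed low with every protein. MED18 had differences of -2.10 (METTL3), -1.31 (METTL14) and -1.29 (METTL16), and CXorf56 of -1.60, -1.01 and -0.80. RPLP0 and RPS2 fell with METTL3 and METTL14, by 2.08 and 1.15 and by 2.04 and 0.89. Relative to the median gene, snoRNAs as a class stood at 1.74, 1.36 and 0.66, lncRNAs at 0.16, 0.00334 and -0.27, and protein-coding genes at -0.045, -0.016 and 0.026.

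Rises that follow gene span could mark unspliced RNA, since long genes hold more intron. Over 11639 protein-coding genes Spearman's rho between span and difference was 0.109 (METTL3), 0.0295 (METTL14) and 0.109 (METTL16). The value of 0.0295 lies under the size of 0.1 set in advance, so over all protein-coding genes the rises did not follow span with all 3 proteins. Span is a stand-in for intron content. A correlation over all genes cannot exclude unspliced RNA among the genes that rose most. For METTL3 and METTL16 alone 0.109 lies between the sizes against and for it (0.1 and 0.2), so span stays open there. Reads over introns, not analysed here, would test for unspliced RNA directly.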
